A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

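The study cloned fragments of the yeast genome as inserts into reporter plasmids and read, for each insert, its abundance in plasmid DNA and in cDNA made from the transcribed RNA. Most inserts had fixed ends, since 24564 of 26816 started with CGA and ended with TCG. Per the labels, cells of the laboratory strain BY4741 grew at 30 °C in medium with 2% galactose, 4 flasks were started at an optical density of 0.025 as biological replicates, and the cultures were harvested after about 10 hours at an optical density of 0.5. Inserts were amplified from plasmid DNA or from cDNA by 20 cycles of PCR with barcoded primers, per the labels' protocols, and no molecular identifiers are described. The deposited values were read counts per insert, whole numbers with a different total in each library. Reads were trimmed and aligned with cutadapt and Bowtie2, per the submitters' processing notes, and their versions and the genome build are not given in the sources used here. How reads were assigned to inserts is also not given there.

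The 3 GEO samples held 6 count tables, each with 2 plasmid DNA and 2 cDNA libraries, 24 libraries in all. The first GAL table came from 2 GEO samples and the other 5 tables from 1 GEO sample. Each table was assigned by its name, matched to the strains the labels list: a second wild-type GAL table and tables for strains lacking UPF1, DHH1 and XRN1. The fifth table of the panel is named RPL4, and that it holds a library under a ribosomal protein promoter is taken from knowledge of the study, since the labels name neither its promoter nor its strain. The labels do not say which flasks the 2 numbered replicates of a table are, so the tests of single inserts measure the spread between these libraries only. The assay reads plasmid inserts and cannot show that a chromosomal gene was deleted, so the tables are called by their names. Columns that matched no sample numbered 0.

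Each insert's chromosome, start, end, strand and sequence were read from the deposited insert names, with the start printed from base 1. The build is unnamed, and gene names came from the S288C annotation of assembly R64. As a check of the coordinates, 1557 of 1557 annotated start codons and 1289 of 1289 stop codons that lay inside an insert were found at the annotated place. An insert was assigned to a protein-coding gene's reading frame where it overlapped the gene by at least 90%. Inserts whose sequence stood at more than 1 position numbered 2083 of 26816 and are described as repeated, because their reads have no certain origin. Such copies were kept as separate inserts in counts of calls and in gene lists. Members of a list that share a sequence, as in ribosomal DNA, are therefore not independent.

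RNA relative to plasmid DNA was tested per insert with edgeR 4.0.16 (quasi-likelihood test, TMM scaling) for inserts with a mean of at least 20 plasmid DNA counts per library, once per table. The UPF1, DHH1, XRN1 and RPL4 tables were then each compared with the second GAL table by the interaction of molecule and table. These 4 comparisons share the second GAL libraries, so they are not independent. Calls had a two-sided Benjamini-Hochberg adjusted p below 0.05 over all inserts tested. Gene sets were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation. The alternative test was the Wald test of DESeq2 1.42.0. A table's named inserts are the 10 called inserts with the highest and the 10 with the lowest log2 fold change, and up to 4 called members of each gene list. The text prints those with a named gene and, where both strands or several members of a list were called, examples of each.

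For the group measures, log2 of RNA over plasmid DNA was computed per insert with a pseudocount of 1 after scaling by library totals. The in-frame stop effect is the median over inserts without a stop codon in a given frame (open inserts) minus the median over inserts with 1. The native reading frame effect compares sense inserts in the gene's own frame with all other inserts of protein-coding genes, sense in other frames or antisense. Codon usage was a codon adaptation index from 35 fragments inside 19 ribosomal protein genes (2239 codons), correlated across inserts by Spearman's rho. Groups were compared by two-sided permutation tests with 100000 draws, whose smallest p is 1e-05. Intervals are 95% bootstrap intervals over inserts. Inserts are not independent replicates, so the stop effects in the frame from base 2 are also given per replicate. For the relations to codon usage and to the stop position, a comparison with the second GAL table is the rho of the per-insert change with the measure, not a difference of 2 rhos. The family held 172 effects, over which Benjamini-Hochberg adjusted values were computed. A test on whole libraries, 2 against 2, cannot give an exact p below 0.333. These intervals cover the spread between inserts, and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Where all cDNA libraries of a group held 0 counts, the fold is a lower bound from a floor of 3 counts over both cDNA libraries.

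The tables, comparisons, tests, gene lists, thresholds and most alternatives were chosen before the data were examined. The frame planned as the main frame started at base 1 of the insert, with the other 2 frames for comparison. The stop effect lay in the frame from base 2, so that frame is reported, and the native frame and codon measures in it, the distance from the stop to the insert's end, the bins of length and GC content, the open share among calls and the tests without repeated inserts or without 100 abundant DHH1 inserts were chosen after the data were seen. The 12 gene lists were ribosomal proteins, glycolysis, translation elongation factors, heat shock proteins, histones, galactose genes, mRNA decay factors, seripauperins, transposon Ty, the mitochondrial genome, ribosomal DNA and transfer RNA genes. The histone list and the transposon Ty list matched 0 inserts each, and the gene table names no Ty elements. Alternatives were DESeq2 size factors, library totals only, no filter or a higher plasmid DNA minimum of 100, a lower minimum of 5 for the group measures, pseudocounts of 0.5 and 5, a replicate block, inserts seen in every cDNA library, no mitochondrial, ribosomal or transfer RNA inserts, the share of optimal codons, and each library left out in turn. When 1 library of an arm is left out, the lone library is assumed to vary like the others.

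On simulated counts drawn from the second GAL table's 7149 inserts, edgeR recovered 6.0% of 100 inserts changed 2-fold and 47% of 100 changed 4-fold. For the UPF1 comparison over 7669 inserts it recovered 1.0% and 16%. In these simulations 3 unchanged inserts of the second GAL table and 0 of the UPF1 comparison were called. The group measures recovered a simulated shift of 0.50 as 0.53 over the second GAL inserts. Most single inserts changed 2-fold were not called in them. Statistics were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and in R 4.3.3. Figures were drawn with matplotlib 3.10.9.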

Results

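Abundance of 26816 genomic inserts was measured in plasmid DNA and in RNA of budding yeast, in 6 tables of 2 plasmid DNA and 2 cDNA libraries each. The inserts had a median length of 199 bases, and 23941 overlapped an annotated gene, 11820 of them in the sense and 11558 in the antisense direction of a protein-coding gene. A share of 26.7% had no stop codon in the frame from base 2 of the insert. The first GAL table held 9442 inserts, with totals of 6031356 and 4216927 plasmid DNA counts and 4595455 and 1017560 cDNA counts. Its plasmid DNA replicate 1 had 2468 inserts at 0 counts, against 0 such inserts in replicate 2, and its cDNA replicate 2 had 1407. Such inserts could still be tested, since the filter used the mean of the 2 plasmid DNA libraries. The second GAL table held 18087 inserts (578656 and 475296 plasmid DNA, 1965190 and 2959846 cDNA), and the RPL4 table held 17955 (3112284 and 3473420, 2135963 and 2209390). The UPF1 table held 19075 (220648 and 627176, 1901466 and 3662235), the DHH1 table held 22420 (582701 and 470437, 2027324 and 1971963) and the XRN1 table held 18179 (284532 and 443572, 380218 and 1015633). Replicate plasmid DNA libraries correlated across inserts least in the first GAL table (Spearman's rho 0.518) and most in the DHH1 table (0.929), and replicate cDNA libraries between 0.888 in the first GAL table and 0.980 in the RPL4 table.

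The wild-type tables asked which features of a transcribed sequence set its RNA level under the galactose promoter. Inserts open in the frame from base 2 had more RNA per plasmid DNA than inserts with a stop codon in that frame, by a median of 1.67 log2 units in the first GAL table (95% interval 1.503 to 1.808; 1.53 and 1.92 in the 2 replicates; 2621 open and 6257 stop inserts). In the second GAL table the difference was 0.80 (0.74 to 0.85; 0.82 and 0.82; 2323 and 4826 inserts). The permutation p was 1e-05 in both tables, the smallest the permutations can give (adjusted p 2.10e-05, permutation tests over 172 effects, two-sided). As a list, open inserts had camera adjusted p = 1.18e-08 in the first and 5.46e-15 in the second GAL table, lost at an adjusted p = 0.169 and adjusted p = 0.198 with an estimated correlation. In the second GAL table the frame from base 3 gave 0.067 and the frame from base 1 gave 0.029 (permutation p = 0.317, adjusted 0.377). In the first GAL table the frames from base 1 and base 3 gave 0.38 and 0.60, but -0.48 and -0.096 within bins of length and GC content, and the former was 0.70 without replicate 1 and 0.14 without replicate 2. Over 10 alternatives, which included these bins, the effect from base 2 in that table ranged from 1.29 to 1.92. RNA of stop inserts fell with the number of bases behind the stop, from a median of -0.29 relative to open inserts within 30 bases of the insert's end to -1.89 at 200 to 300 bases in the second GAL table, and from -0.021 to -4.45 in the first, where RNA of open inserts also fell with insert length (rho -0.49). In the first GAL table the replicates gave -0.24 and 0.052 within 30 bases, and -4.69 and -4.61 at 200 to 300 bases. Across stop inserts, rho with the bases behind the stop was -0.50 in the first and -0.35 in the second GAL table.

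**Figure D1:**
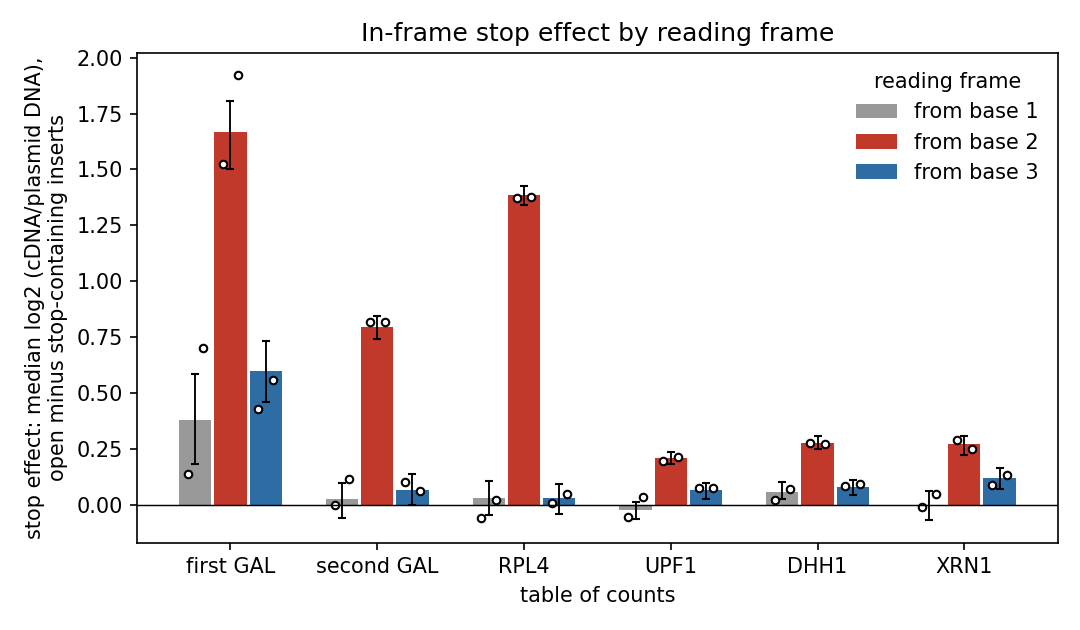
Median log2 of RNA over plasmid DNA of inserts without a stop codon minus that of inserts with 1, for each table and each of the 3 reading frames; bars are tables, error bars are 95% bootstrap intervals over inserts and open circles are the 2 replicates. The frame from base 2 reached 1.67 in the first GAL table and 1.39 in the RPL4 table, and stayed between 0.21 and 0.28 in the UPF1, DHH1 and XRN1 tables.

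Sense inserts in their gene's own frame from base 2 were higher than the other inserts of protein-coding genes, out of frame or antisense, by 1.23 in the first GAL table and 0.70 in the second. Most of the latter were antisense. With the gene's frame from base 1 or base 3 the values were -0.64 and 0.025 in the first and -0.015 and -0.22 in the second GAL table. Of the native-frame inserts 1877 were open and 120 had a stop in the first GAL table, and 1591 and 77 in the second. Among open inserts alone the native frame effect was 0.14 in the second GAL table, and 0.27 in the first, where the permutation p was 0.289 and the replicates gave 0.148 and -0.019. Over open sense inserts of other frames the native frame had no lead in the second GAL table, where open inserts had a median of 0.43 in the native frame, 0.52 in other sense frames (148 inserts) and 0.24 in the antisense direction (436 inserts). In the first GAL table it had a lead, with medians of 0.37, -0.59 (204 inserts) and 0.54 (391 inserts) in the same order. In the second GAL table, native-frame inserts with a stop had a median 0.20 below that of all open inserts, antisense inserts with a stop fell by 0.85, and open antisense inserts by 0.14. No single insert passed an adjusted p of 0.05 by edgeR in either table: 0 of 8878 in the first, with 2714 at an unadjusted p below 0.05 and 3825 calls by DESeq2, and 0 of 7149 in the second, with 2203 at an unadjusted p below 0.05 and 1069 calls by DESeq2. Counts of calls depended on which molecule was left with a single library, more than on which of its replicates was dropped. Of the first GAL inserts 4924 were called without plasmid DNA replicate 1 and 5732 without replicate 2. Of the second GAL inserts 4630 were called without plasmid DNA replicate 1, 4592 without replicate 2, 18 without cDNA replicate 1 and 66 without cDNA replicate 2. Without a filter on low counts the second GAL table gave 1654 calls. With a replicate block edgeR called 1103 inserts in the second GAL table and 0 in the first. Scaling by library totals only shifted the median insert to -1.47 in the first and -0.23 in the second GAL table.

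The RPL4 table, taken to hold a library under a ribosomal protein promoter, asked the same question, and single inserts could be named in it. The highest were inserts in their gene's own frame: YKL091C, a Sec14-like protein (chromosome XI, 270275 to 270387), at a log2 RNA over plasmid DNA of 4.19 (SE 0.73, n = 2 libraries of each molecule); SGM1, a Golgi protein, at 3.95 (SE 0.32); ESL2 at 3.90 (SE 0.69); and SRB5, a Mediator subunit, at 3.79 (SE 0.79). RQC1, of the ribosome quality control complex, followed at 3.46, the NAD synthesis gene NMA2 at 3.37, SRL4 at 3.36, the Golgi nucleotide-sugar transporter VRG4 at 3.29 and the drug transporter AQR1 at 3.28. The only other insert among the 10 highest was antisense to the glucanase gene DSE4, at 3.40, and it too was open. The 10 inserts with the lowest fitted values all had a stop codon in the frame from base 2 and 0 cDNA counts. An out-of-frame insert of CDC43, which encodes a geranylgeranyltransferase subunit, was at least 65.9-fold lower in RNA, and 182 bases lay behind its stop. Inserts antisense to the spore wall gene DIT2, the iron-sulfur cluster gene NFU1, the phosphate transporter gene PHO87 and the telomere length gene TEL2 were at least 43.3-, 39.7-, 32.9- and 30.3-fold lower. An insert of the autophagy gene HSV2 in another frame was at least 34.1-fold lower. Inserts without a gene on chromosome II from 29237 and chromosome VII from 352580 were at least 41.9- and 33.6-fold lower. Inserts antisense to YOR192C-B and YBL100W-B were at least 35.4- and 33.4-fold lower, with uncertain origin because their sequence is repeated.

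Inserts of 1 gene could stand far apart in the RPL4 table. The same 155 bases of DHH1, the decay helicase gene (chromosome IV, 170889 to 171043), stood at 3.21 (SE 0.28) in the sense, native-frame direction and at -3.52 (SE 0.31) in the antisense direction. Inserts of SSC1, a mitochondrial Hsp70, stood at 3.00 (SE 0.42) in the native frame and at -3.39 (SE 0.46) in an antisense insert that was open. Native-frame inserts of elongation factor 2 (EFT1) reached 3.21, ribosomal protein RPS8A 2.94, the chaperone SSA1 2.77, the exonuclease XRN1 2.60, ribosomal stalk protein RPP2A 2.21 and the glycolytic enzyme ENO1 2.09. An out-of-frame insert of the elongation factor gene CAM1 fell to -3.05, and an antisense insert of the glycolytic gene HXK1 to -2.72. In total edgeR called 3051 of 13416 inserts, 1595 higher and 1456 lower. Open inserts made up 74.2% of the higher, 4.33% of the lower and 28.7% of the tested inserts. DESeq2 called 3578. Scaling by library totals only shifted the median insert to -0.42 and gave 994 higher and 2053 lower. The count rose when either plasmid DNA library was left out and fell to few inserts when either cDNA library was. It therefore depended on which molecule kept its replicates, more than on any single library. Replicate plasmid DNA libraries spread further beyond counting error than replicate cDNA libraries (chi-square per degree of freedom 27.8 against 2.51). All 3051 calls had the same sign in every library.

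Among gene groups of the RPL4 table, open inserts were called 1184 times higher and 63 times lower of 3853 (camera adjusted p = 9.81e-36, and adjusted p = 0.0152 with an estimated correlation). Ribosomal DNA inserts had a median of -4.52, or -4.23 with the 2 inserts at 0 counts set to their bound, with 13 lower and 8 higher of 31 (camera adjusted p = 1.72e-10, and adjusted p = 0.0640 with an estimated correlation), and adjusted over the list alone 18 were lower. An insert of the ribosomal RNA gene RDN37-2 (chromosome XII from 461448), of repeated sequence, stood at -7.25 (SE 0.12). Transfer RNA genes had a median of -1.64, with 34 lower and 3 higher of 110 (camera adjusted p = 9.56e-08, and adjusted p = 0.0640 with an estimated correlation), and 39 lower adjusted over the list alone. Inserts of glycolytic genes had a median of 0.66, with 18 higher and 9 lower of 58, or 26 and 11 adjusted over the list alone (camera adjusted p = 0.00205, and adjusted p = 0.131 with an estimated correlation). Heat shock genes had 20 higher and 9 lower of 54 and elongation factors 6 and 1 of 25, with camera adjusted p = 0.0309 for each and adjusted p = 0.199 with an estimated correlation. Ribosomal protein genes had 15 higher and 5 lower of 78, with a median of -0.0057 against -0.15 for all other inserts (set test up). The counts were 5 and 6 of 36 for mRNA decay factors, 2 and 0 of 17 for seripauperins (median -0.31, set test up) and 1 and 0 of 12 for galactose genes. The stop effect in the frame from base 2 was 1.39 (1.34 to 1.43; 1.37 and 1.38; 3853 and 9563 inserts), against 0.033 and 0.031 in the frames from base 1 and base 3. Stop inserts fell from -0.28 within 30 bases of the end to -2.71 at 200 to 300 bases (rho -0.47), and the native frame effect was 1.28.

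The deletion tables asked whether the stop effect needs mRNA decay factors. The UPF1 table, named after the helicase of nonsense-mediated decay, showed a stop effect of 0.21 in the frame from base 2 (0.18 to 0.24; 0.20 and 0.22; 2544 open and 5220 stop inserts; camera adjusted p = 4.00e-04 for open inserts as a list, and adjusted p = 0.640 with an estimated correlation). Over the inserts shared with the second GAL table the effect was smaller by 0.50 (difference -0.50, interval -0.55 to -0.45), at 0.22 and 0.20 in the UPF1 replicates against 0.73 and 0.73 in the GAL replicates. Stop inserts of the UPF1 table stood at -0.18 within 30 bases of the end and at -0.24 at 200 to 300 bases, where the replicates gave -0.0027 and -0.43. The rise over the second GAL table grew with that distance (rho 0.28 across stop inserts), but within the UPF1 table rho itself was 0.046 in replicate 1 and -0.125 in replicate 2. The native frame effect was 0.21, and lower than in the second GAL table by 0.38 (difference -0.38). Open inserts had a median change of -0.28 against the second GAL table, and stop inserts 0.23 (camera adjusted p = 5.54e-06, and adjusted p = 0.224 with an estimated correlation). Permutation p was 1e-05 for these differences in stop and frame effects, and the exact library test gave 0.333, its smallest value. With at least 100 plasmid DNA counts, 158 inserts were left and the stop effect was 0.015, no longer past the threshold.

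Single inserts of the UPF1 table did not pass the threshold by edgeR without a replicate block. With a block 201 passed for RNA against plasmid DNA, and 0 against the second GAL table. Without it the counts were as follows. edgeR called 0 of 7764 for RNA against plasmid DNA, with 1067 at an unadjusted p below 0.05 and 13 calls by DESeq2, and 0 of 7669 against the second GAL table, with 1393 at an unadjusted p below 0.05 and 242 calls by DESeq2. The first count was 1 or 4 without plasmid DNA replicate 1 or 2, 17 without cDNA replicate 1 and 459 without cDNA replicate 2. The second was 1143 without second GAL plasmid DNA replicate 1, 516 without replicate 2 and 2 with at least 100 plasmid DNA counts. Against the second GAL table, ribosomal DNA inserts had a median of 0.87, transfer RNA genes 0.53, glycolytic genes -0.23 and elongation factors -0.42. None of these lists passed as a set (camera adjusted p = 0.224, 0.465, 0.465 and 0.224 in that order). Adjusted over each list alone, edgeR called 1 glycolytic, 2 elongation factor and 1 seripauperin insert lower.

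The DHH1 table, named after a helicase that activates decapping, was dominated by few inserts. The 100 inserts with most cDNA counts held 82.6% and 73.3% of the cDNA reads of its libraries and 10.5% and 6.60% of its plasmid DNA reads, against 1.66% and 1.62% of plasmid DNA in the second GAL table. Inserts of GRR1, an F-box protein, stood at 7.11 (SE 1.86), ROM2, a Rho1 exchange factor, at 7.09 (SE 1.02), the cell wall gene PST1 at 6.99 (SE 1.76), the DNA helicase SRS2 at 6.95 (SE 1.496), and inserts antisense to ALD2 and TOS2 at 6.90 and 6.87. The clathrin gene CHC1, the iron transport gene FIT1, the clathrin adaptor ENT5 and SMT1 each stood at 6.87. All of these but the ROM2 insert belonged to the 100. High ratios of RNA to plasmid DNA were not limited to the 100. In replicate 1, as many as 260 inserts lay at least 4 log2 units above the median ratio. The inserts with the lowest fitted values had too few cDNA counts for a fold: 1 in total for a native-frame insert of the Ras regulator IRA2, 2 antisense to ribosomal protein RPL3, 2 for the mannosyltransferase VAN1, and 3 each for ATO2, VPS13, RNR3 and YNL035C. An out-of-frame insert of the splicing gene MRS1 was at -2.78 (SE 0.65), YBL044W at -2.55 and an antisense insert of the prefoldin gene PAC10 at -2.50. The IRA2 value rested on plasmid DNA replicate 2, without which its fitted log2 fold change was 0.078. edgeR called 1170 of 8775 inserts, 807 higher and 363 lower, with 43.1% and 9.09% open (Fisher's exact p = 1.58e-34), and DESeq2 called 444.

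Counts in the DHH1 table changed with scaling and with the libraries left out. Scaling by library totals only shifted the median insert to -3.18 and gave 216 higher and 8442 lower, and with at least 100 plasmid DNA counts 296 of 301 inserts were called. Without plasmid DNA replicate 1 or 2 the count was 524 or 428. Of gene lists, glycolysis had 7 higher and 3 lower of 46, elongation factors 2 and 0 of 20, heat shock proteins 3 and 1 of 41, mRNA decay factors 3 and 3 of 23, ribosomal proteins 3 and 4 of 46, seripauperins 1 and 0 of 13, ribosomal DNA 2 and 6 of 29 and transfer RNA genes 2 and 9 of 72. The stop effect in the frame from base 2 was 0.28 (0.25 to 0.31; 0.28 and 0.27; 2791 and 5984 inserts), with camera adjusted p = 1.91e-04 for open inserts as a list, and adjusted p = 0.0516 with an estimated correlation. It was 0.18 with a pseudocount of 5 and 0.55 over 301 inserts with at least 100 plasmid DNA counts. It lay below that of the second GAL table by 0.43 (difference -0.43, interval -0.49 to -0.38; 0.27 and 0.25 against 0.71 and 0.74; permutation p = 1e-05, exact library p = 0.333), and -0.43 without the 100 abundant inserts. Stop inserts fell from -0.083 within 30 bases of the end to -0.74 at 200 to 300 bases (rho -0.29), but RNA of open inserts fell with insert length as well (rho -0.27). The native frame effect was 0.24, a difference of -0.40, and over 226 inserts with at least 100 plasmid DNA counts it was 5.02.

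Against the second GAL table, an insert antisense to the silencing gene ESC8 rose in the DHH1 table by 8.65 (SE 0.75), and inserts of PAN3, a deadenylase subunit, by 8.45 (SE 1.25), the tRNA methylation gene TRM82 by 8.45 (SE 1.14), DDE1 by 8.15 and SRS2 by 8.12. Inserts antisense to the methionine salvage gene MDE1 and the vacuolar transporter gene YCF1 rose by 8.288 and 8.003. The inserts of PAN3, TRM82, DDE1 and SRS2 and the MDE1 insert belonged to the 100 abundant inserts. An insert of the pseudogene AAD6 had 2 cDNA counts in the second GAL table and 1165 and 1141 in the DHH1 libraries. Among the inserts that fell were native-frame inserts of GOR1, a glyoxylate reductase (-3.31, SE 0.46), SEC6 of the exocyst (-3.24, SE 0.61), the NAD synthesis gene BNA5 (-2.82, SE 0.47), the glycolytic enzyme TDH1 (-2.71, SE 0.49) and GTA1 (-2.69, SE 0.58). Inserts antisense to the exocyst regulator SEC2, ubiquitin gene UBI4, RIM1 and TOG1 fell to -3.99, -3.20, -2.96 and -2.88, and an out-of-frame insert of the spore wall gene SPS100 to -2.91. Of 30 ribosomal DNA inserts 13 rose and 0 fell, with a median of 1.92 (camera adjusted p = 2.43e-07, and adjusted p = 0.142 with an estimated correlation). Open inserts rose 95 times and fell 46 times of 2621, and the median of all of them was -0.25 (camera adjusted p = 0.00182, and adjusted p = 0.142 with an estimated correlation).

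For this comparison the counts were 436 of 8123 inserts by edgeR, 353 higher and 83 lower, and 463 by DESeq2. Of the higher inserts 26.9% were open, and of the lower 55.4% (Fisher's exact p = 1.71e-06). The count was 0 without DHH1 plasmid DNA replicate 1 and 0 without replicate 2. It was 25 and 110 without second GAL cDNA replicates 1 and 2, 289 without DHH1 cDNA replicate 1, and 2406 and 2076 without second GAL plasmid DNA replicates 1 and 2. Without the 100 abundant inserts it was 275 (222 higher and 53 lower), with no filter 713 and with at least 100 plasmid DNA counts 152. The 275 may still hold inserts of similarly high ratio, since high ratios in the DHH1 libraries were not limited to the 100. Scaling by library totals only shifted the median to -2.99 and gave 184 higher and 6560 lower.

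The XRN1 table, named after the main 5' to 3' exonuclease, had its highest values at inserts of SIN3, a histone deacetylase subunit (chromosome XV, 317807 to 317987), at 2.17 (SE 0.28), RDL2 at 2.08 (SE 0.29), the GTPase RHB1 at 1.97 (SE 0.26) and OSW7 at 1.94 (SE 0.28). Inserts antisense to the kinase PTK2 and the methionine permease MUP1 stood at 1.92 and 1.82, ZDS2 at 1.85, the permease-sorting gene LST4 at 1.81 and the ribosome assembly gene PNO1 at 1.79. An out-of-frame insert of TUB2, beta tubulin, was at least 34.1-fold lower in RNA, a bound that rested on plasmid DNA replicate 2 (2 and 54 counts), without which the insert was not called. Inserts of the ribosomal RNA genes RDN37-1 and RDN37-2 made up most of the other low values, from -3.94 (SE 0.30) to -3.49, while another RDN37-1 insert stood at 1.799, all with repeated sequence. An antisense insert of YIP5 was at -3.59 (SE 0.85). Native-frame inserts of ribosomal protein genes RPS8A and RPS8B were at 1.499 and 1.498 and antisense inserts over the same bases at -2.0001 and -1.65, again with sequence shared between the 2 genes. edgeR called 858 of 6345 inserts, 455 higher and 403 lower, with 51.2% and 21.3% open (Fisher's exact p = 6.34e-20), and 857 of the 858 had the same sign in every library. Ribosomal DNA had 2 higher and 15 lower of 29, transfer RNA genes 1 and 16 of 50 (camera adjusted p = 7.17e-12 and 2.18e-09, and adjusted p = 0.330 with an estimated correlation for each). Glycolysis had 7 higher and 4 lower of 37, heat shock proteins 4 and 3 of 26, ribosomal proteins 3 and 3 of 32, mRNA decay factors 2 and 2 of 17, elongation factors 2 and 1 of 15 and seripauperins 1 and 1 of 7.

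Counts for the XRN1 table were 283 by DESeq2, 2622 with no filter and 12 of 183 with at least 100 plasmid DNA counts. Without plasmid DNA replicate 1 or 2 they were 20 or 6, without cDNA replicate 1 298 and without cDNA replicate 2 582. Library totals only shifted the median to -0.19 and gave 225 higher and 484 lower. The stop effect in the frame from base 2 was 0.27 (0.23 to 0.31; 0.29 and 0.25; 2164 and 4181 inserts), smaller than in the second GAL table by 0.41 (difference -0.41, interval -0.47 to -0.35; 0.30 and 0.27 against 0.71 and 0.72; permutation p = 1e-05, exact library p = 0.333). Over 183 inserts with at least 100 plasmid DNA counts it was 0.15, no longer past the threshold. The rise of stop inserts over the second GAL table grew with the bases behind the stop (rho 0.21 across inserts), and the native frame effect of 0.28 was lower by 0.36 (difference -0.36). Against the second GAL table, open inserts had a median change of -0.20 and stop inserts 0.22 (camera adjusted p = 3.33e-04, and adjusted p = 0.0406 with an estimated correlation). No single insert passed in that comparison: edgeR called 0 of 7025, with 1324 at an unadjusted p below 0.05 and 121 calls by DESeq2. Without second GAL plasmid DNA replicate 1 or 2 it called 1557 or 1242. Adjusted over each list alone, edgeR called 2 heat shock inserts higher and 1 lower, 2 seripauperin inserts higher and 1 elongation factor insert lower.

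The RPL4 table was compared with the second GAL table to ask whether the promoter, which the labels do not name, changes the response to the transcribed sequence. The stop effect was larger in the RPL4 table by 0.56 (interval 0.50 to 0.62; 1.27 and 1.31 against 0.77 and 0.78; permutation p = 1e-05, exact library p = 0.333). The native frame effect was larger by 0.46, and stop inserts fell further with the bases behind the stop (rho of the change -0.21). The RPL4 plasmid DNA libraries were also deeper (3112284 and 3473420 counts against 578656 and 475296). In the first GAL table, under the galactose promoter, the stop effect was 1.67. The part of the promoter in these differences therefore cannot be told apart from other differences between tables. Inserts of the meiotic SUMO ligase CST9, the rRNA exonuclease RRP17 and the poly(A) polymerase PAP1 rose by 7.94 (SE 0.40), 7.60 (SE 0.51) and 6.90 (SE 0.56), and inserts antisense to the dynactin gene JNM1, the phosphatase gene PTC4 and the GTPase gene YPT10 by 8.50, 7.06 and 6.22. These 6 had between 2 and 11 plasmid DNA counts in each RPL4 library, and an insert antisense to SEC23 had 1 in each. A native-frame insert of the microtubule gene MHP1 rose by 6.17 (SE 0.98). Inserts of the Golgi gene GMH1, the vacuolar ATPase YPK9, the nuclease subunit MMS4 and the clathrin adaptor ENT3 fell to -5.98 (SE 0.86), -5.11 (SE 0.79), -4.31 (SE 0.65) and -3.94 (SE 0.59). Inserts antisense to the initiation factor gene TIF5 and the proteasome gene ECM29 fell to -5.30 and -3.87. Their second GAL plasmid DNA counts were as low, between 2 and 17 per library.

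edgeR called 72 of 11759 inserts in this comparison, 45 higher and 27 lower, with 48.9% and 11.1% open (Fisher's exact p = 0.00178), and DESeq2 called 935. Open inserts were 22 times higher and 3 times lower of 3505, or 62 and 14 adjusted over the list alone, with a median of 0.38 (camera adjusted p = 8.95e-05, and adjusted p = 0.0322 with an estimated correlation). Of 30 ribosomal DNA inserts 1 rose and 3 fell, and the riser was 15S_RRNA, the only called insert of 5 from the mitochondrial genome, at 2.92. Transfer RNA genes had 0 called of 91, with a median of -0.34, and glycolysis 0 of 53, with 0.42. The count of calls was 1017 and 918 without RPL4 plasmid DNA replicates 1 and 2, 9 and 10 without RPL4 cDNA replicates 1 and 2, 1138 and 711 without second GAL plasmid DNA replicates 1 and 2, and 9 and 5 without second GAL cDNA replicates 1 and 2. It was 169 with no filter, 233 with at least 100 plasmid DNA counts, and 45 with library totals only, 23 higher and 22 lower.

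Codon usage, GC content and length were also related to RNA per plasmid DNA across inserts, which are not independent replicates. Read in the frame from base 2, chosen after the data were seen, inserts richer in the codons of ribosomal protein genes had slightly more RNA: rho was 0.050 in the first GAL table, 0.079 in the second, 0.082 in the RPL4 table, 0.058 in the UPF1 and DHH1 tables and 0.048 in the XRN1 table. In the planned frame from base 1 it was -0.045, 0.038, 0.025, -0.010, -0.012 and 0.0093 in the first GAL, second GAL, RPL4, UPF1, DHH1 and XRN1 tables, and from base 3 -0.058, -0.049, -0.068, -0.0024, -0.040 and -0.019. Given GC content and length, the relation in the frame from base 2 was computed with 1 replicate left out at a time. It was 0.088 to 0.095 in the first GAL, 0.093 to 0.110 in the second GAL and 0.107 to 0.110 in the RPL4 table. In the UPF1, DHH1 and XRN1 tables it was 0.067 to 0.071, 0.090 to 0.097 and 0.070 to 0.080. Over inserts with at least 100 plasmid DNA counts the codon relation had the other sign in the UPF1 (-0.041, 139 inserts) and XRN1 tables (-0.284, 142 inserts). The change of an insert from the second GAL table correlated with codon usage at rho -0.044 for the UPF1 table (permutation p = 3.90e-04), -0.029 for the XRN1 table (p = 0.023, adjusted 0.034) and -0.020 for the DHH1 table (p = 0.095, adjusted 0.126), and at -0.028, -0.023 and -0.031 in the frame from base 1. GC-rich inserts had more RNA in all 6 tables, with rho from 0.14 in the UPF1 table to 0.31 in the first GAL table. In the DHH1 table GC content and length had the other sign over 301 inserts with at least 100 plasmid DNA counts (-0.226 and 0.281). Longer inserts had less RNA in the first GAL (rho -0.56), second GAL (-0.22), RPL4 (-0.27) and DHH1 tables (-0.36), and rho was 0.031 in the UPF1 and -0.037 in the XRN1 table. The last 2 changed sign between replicates, at -0.117 without replicate 1 and 0.127 without replicate 2 of the UPF1 table, and at -0.155 and 0.061 for the XRN1 table. Among open inserts the relation with length was close to 0 in the second GAL (0.034) and RPL4 tables (0.010), and stayed at -0.49 in the first GAL and -0.27 in the DHH1 table. With 1 replicate left out at a time it was 0.033 to 0.240 in the UPF1 and -0.014 to 0.231 in the XRN1 table. RNA per plasmid DNA of the same inserts correlated most between the DHH1 and XRN1 tables (rho 0.54 across 6043 inserts) and the second GAL and RPL4 tables (0.49 across 6139), and least between the first GAL and UPF1 tables (0.22 across 4823).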

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

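The tests of a loss of decay and the measures in the frame from base 2 were chosen after the result was seen, while the tests of depth and of plasmid DNA carry-over were set before. Each value below stands out by a test of the difference from the second GAL table itself. Values for the share before the stop, the bases behind the stop and codon usage are correlations of the per-insert change with that measure. In the UPF1 table the stop effect in the frame from base 2 differed by -0.50 and the native frame effect by -0.38, and the change correlated with the share of the insert before the stop at -0.20, with the bases behind the stop at 0.284 and with codon usage at -0.0437. In the DHH1 table the corresponding values were -0.43, -0.156, 0.154 and -0.40, in the order stop effect, share before the stop, bases behind the stop and native frame. The correlation with the bases behind the stop within its own libraries was -0.178 and -0.287, against -0.274 and -0.271 in the second GAL libraries (library difference 0.040, the exact library test not passed). In the XRN1 table they were -0.41, -0.193, 0.214 and -0.36, with -0.0295 for codon usage and 0.11 for the stop effect in the frame from base 3. In the RPL4 table they were 0.56, 0.178, -0.209 and 0.46, with 0.0264 for codon usage and -0.062 for the frame from base 3. Single inserts differed from the second GAL table in 436 cases in the DHH1 table and in 72 in the RPL4 table.

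The smaller stop effect of the 3 deletion tables may be technical or may come from the deletions. Over their own inserts, the wild-type GAL tables themselves stood at 1.67 (first) and 0.80 (second) in the frame from base 2. That gap was wider than the difference of any deletion table from the second GAL table. Intervals over inserts do not cover such spread between tables. Thinned to the other tables' depth, the second GAL libraries kept a stop effect of at least 0.66 in 20 draws per table. This argues against depth as the cause in the UPF1 and XRN1 tables. For the UPF1 table mainly plasmid DNA replicate 1 was thinned (220648 against 578656 counts), since its other libraries were nearly as deep or deeper. For the DHH1 table the test cannot decide, since the thinning matched summed counts and 100 inserts held 82.6% and 73.3% of its cDNA reads. Its median cDNA count per insert was 3 and 8, against 35 and 60 in the second GAL table. Carry-over of plasmid DNA into cDNA would have to make up shares of 0.71, 0.61 and 0.64 of the UPF1, XRN1 and DHH1 cDNA reads. The covariance of open inserts with the RPL4 table lay above that of such a mixture by 0.0824 (interval 0.0546 to 0.110) in the UPF1 table. In the XRN1 table it lay above by 0.0635 (0.0348 to 0.0895). That argues against carry-over as the whole cause in these tables. It does not exclude it, since the intervals cover inserts only and the mixture was built from second GAL cDNA. In the DHH1 table the difference was -0.00366 (-0.0355 to 0.0299), and carry-over stays open there. Loss of decay of transcripts with a long stretch behind the stop needs a rise over the second GAL table that grows with that stretch, and the correlation was 0.284 in the UPF1, 0.214 in the XRN1 and 0.154 in the DHH1 table, values that carry-over would give as well. The tables also came from libraries whose strain could not be checked and whose preparation batches are not given, so the part of the deletion itself stays a hypothesis.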

How the results depend on the processing

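The alternatives without repeated inserts, without the 100 abundant DHH1 inserts, in length and GC bins and with crossed replicate numbers were chosen after the results were seen. The stop effect in the frame from base 2 kept its direction in all 110 alternatives over the 6 tables and 4 differences. The length and GC bins among them were judged by direction alone, without a test. Within these bins the differences were -0.45 for UPF1, -0.45 for DHH1, -0.41 for XRN1 and 0.52 for RPL4. The stop effect was no longer past the threshold in 2 alternatives, both with at least 100 plasmid DNA counts. These were the UPF1 table (0.015, 158 inserts) and the XRN1 table (0.15, 183 inserts), where few inserts were left. Of the values of named inserts, 1569 kept direction and call, 628 lost the call and 12 changed sign. The cause of these changes was not tested.

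By DESeq2 the counts of calls were 3825 in the first GAL, 1069 in the second GAL, 13 in the UPF1, 444 in the DHH1 and 283 in the XRN1 table, and 242, 121 and 935 for the UPF1, XRN1 and RPL4 tables against the second GAL table. Without a filter they were 1654 in the second GAL and 2622 in the XRN1 table, 713 for DHH1 and 169 for RPL4 against the second GAL table. With at least 100 plasmid DNA counts they were 296 in the DHH1 and 12 in the XRN1 table, and 2 for UPF1, 152 for DHH1 and 233 for RPL4 against the second GAL table. Library totals only gave 8658 in the DHH1 table, 6744 for DHH1 and 45 for RPL4 against the second GAL table. Without the 100 abundant inserts the DHH1 comparison had 275. In the first GAL table same-numbered plasmid DNA and cDNA libraries belonged to the same GEO sample. The panel tables all came from a single sample, and with 2 pairs per table their replicate numbers do not establish a pairing. Deviations of same-numbered plasmid DNA and cDNA libraries correlated at -0.20 in the first GAL, 0.12 in the second GAL and 0.096 in the RPL4 table. They correlated at 0.24 in the UPF1, 0.11 in the DHH1 and 0.25 in the XRN1 table. With a replicate block edgeR called 0 inserts in the first GAL table (1559 at an unadjusted p below 0.05, 3825 calls by DESeq2), 1103 in the second GAL, 3075 in the RPL4, 201 in the UPF1, 1237 in the DHH1 and 1882 in the XRN1 table. Between tables the block gave 0 calls for UPF1 (1243 at an unadjusted p below 0.05, 242 by DESeq2), 403 for DHH1, 0 for XRN1 (1255, 121 by DESeq2) and 24 for RPL4. Crossed numbers in the first GAL table, which go against its pairing by sample, gave 0 calls by edgeR (1789 at an unadjusted p below 0.05).

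In the planned frame from base 1 the stop effect was close to 0 outside the first GAL table, and other settings moved it. The frame from base 2 gave 0.80 in the second GAL, 1.39 in the RPL4, 0.21 in the UPF1 and 0.27 in the XRN1 table, and the frame from base 3 gave 0.0667, 0.0669 and 0.12 in the second GAL, UPF1 and XRN1 tables. With at least 5 plasmid DNA counts base 1 gave 0.064, 0.039 and 0.098 in these 3 tables, with at least 100 it gave -0.20 in the second GAL and -1.24 in the DHH1 table, and with a pseudocount of 5 it gave 0.011 in the DHH1 table. Differences from the second GAL table were -0.50, -0.43, -0.41 and 0.56 for UPF1, DHH1, XRN1 and RPL4 in the frame from base 2, 0.11 and -0.062 for XRN1 and RPL4 in the frame from base 3, and 0.27 and 0.32 for UPF1 and XRN1 in the frame from base 1 with at least 100 plasmid DNA counts. For the relation to the share of the insert before the stop, the frame from base 2 gave 0.028 in the UPF1 table, and -0.156 and -0.193 as the correlations of the DHH1 and XRN1 change from the second GAL table, and the frame from base 3 gave -0.046 for the XRN1 change.

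With at least 100 plasmid DNA counts (158 inserts in the UPF1, 301 in the DHH1 and 183 in the XRN1 table) further values changed. In the UPF1 table the native frame effect was 0.059, the codon relation -0.041 (-0.037 given GC content and length), GC content 0.049 and length -0.0021. In the DHH1 table the share before the stop gave -0.063 in the frame from base 1 and -0.068 from base 2, the native frame effect was 5.02 (5.07 among open inserts), the codon relation 0.098, bases behind the stop 0.18, GC content -0.226, length 0.281 and length among open inserts 0.48. In the XRN1 table the native frame effect was 0.00386 (-0.34 among open inserts), the codon relation -0.284 (-0.326 given GC content and length), GC content 0.097 and length among open inserts -0.086. With at least 5 plasmid DNA counts the length relation of the UPF1 table was -0.011. Without repeated inserts the native frame effect among open inserts was -0.34 in the first GAL table, and the length relation of the XRN1 table -0.022. The correlation of the change from the second GAL table with codon usage was, for DHH1, -0.026 with a pseudocount of 5, -0.024 with at least 5 plasmid DNA counts and -0.080 among open inserts, for XRN1 -0.012 without repeated inserts and -0.0087 with the share of optimal codons, and for RPL4 0.018 among open inserts. Of 140 correlations between tables under alternatives, 15 moved by more than the replicate spread, to as much as 0.70 between the UPF1 and XRN1 tables with at least 100 plasmid DNA counts.

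Under library totals only, inserts of the DHH1 table changed sign: TEF2 -1.87, PGI1 -1.51, SSC1 -1.94, DAN4 -2.07, SSA2 -0.051 and TEF1 -2.45. Against the second GAL table SSA4 went to -1.24, transfer RNA genes YNCG0003C to -0.47 and YNCJ0015W to -0.36, HXK2 to -0.59 and SSC1 to -0.81. The median insert shifted to -3.18 and -2.99 under this scaling.

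Leaving out 1 library at a time, counts of calls ranged from 0 to 5732 in the first GAL, 18 to 4630 in the second GAL, 7 to 9401 in the RPL4, 1 to 459 in the UPF1, 428 to 916 in the DHH1 and 6 to 582 in the XRN1 table. Against the second GAL table they ranged from 0 to 1143 for UPF1, 0 to 2406 for DHH1, 0 to 1557 for XRN1 and 5 to 1138 for RPL4, and the IRA2 insert of the DHH1 table from -7.80 to 0.078. Without 1 replicate, the base 1 stop effect ranged from 0.00073 to 0.12 in the second GAL table, and its XRN1 difference from 0.0091 to 0.087. The length relation ranged from -0.117 to 0.127 in the UPF1 and from -0.155 to 0.061 in the XRN1 table, and among open inserts from -0.035 to 0.042 in the RPL4 and from -0.014 to 0.231 in the XRN1 table. The relation to the share before the stop ranged from -0.052 to 0.0090 in the UPF1 and from -0.030 to 0.029 in the XRN1 table, and bases behind the stop from -0.125 to 0.046 in the UPF1 table. Correlations of the change with codon usage ranged from -0.025 to -0.011 for DHH1, -0.039 to -0.020 for XRN1 and 0.018 to 0.030 for RPL4.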

Other observations

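The test of a loss of long amplicons was set before its result was seen, and the other tests here after. In the RPL4 table the median log2 RNA over plasmid DNA of native-frame inserts without a stop was 0.72, and that of antisense inserts with a stop -0.77. Open antisense inserts, which encode no natural protein, stood at 0.39, and native-frame inserts that reach their gene's own stop or another stop at -0.14. In the UPF1 table the same 4 groups stood at 0.17, -0.13, -0.0081 and 0.16.

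The 100 inserts that took most cDNA reads of the DHH1 table may reflect a small set of clones. Their share of plasmid DNA was also higher than in the second GAL table, by a median of 3.11 log2 units (interval 2.72 to 3.56) over the 99 found there. This argues against a change of RNA level alone. It does not exclude one, since the test cannot tell a larger plasmid share from cDNA reads counted in the plasmid DNA libraries. Their excess in cDNA followed their excess in plasmid DNA with a Spearman correlation of 0.932 in replicate 1 and 0.870 in replicate 2, across the 96 and 92 inserts with an excess in both. Over all inserts of the DHH1 table, plasmid DNA and cDNA counts already correlated at 0.829 and 0.870. The correlation of the excesses alone therefore does not single out a set of clones. Whether the 100 inserts arose in the culture or in library preparation was not tested.

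The steep fall of RNA with insert length in the first GAL table may come from a loss of long amplicons in its cDNA libraries. Stop codons in long inserts cannot be the whole cause, since the correlation with length was -0.493 among open inserts. A part played by them was not excluded. Against the second GAL table, cDNA counts of 1620 open inserts fell with length (rho -0.326, interval -0.372 to -0.279), while plasmid DNA counts rose (rho 0.257). No biological explanation was tested, since both tables are wild type.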
